A study of Rattus norvegicus with 10 samples.

How the data were processed

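Testes of obese and lean Zucker rats were profiled on 10 Affymetrix rat arrays, with 1 array per sample. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated with the Affymetrix WT PLUS kit. The values deposited by the authors were log2 expression values per probe set, summarised by RMA per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of a probe set, and its settings, software version and genome build were not given in the sources used here. Normalization between arrays assumes that most genes or the overall distribution are alike, so a change in the make-up of a tissue lowers some genes relative to others. Scanner files were not used here, and no slide or scan date was given.

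The table held 36685 probe sets, of which 18511 carried 1 gene symbol in the platform annotation, 575 carried several and 17599 were unnamed here. Symbols were updated through gene numbers against the RefSeq table of assembly GRCr8, in which 18394 probe sets matched, and that table also gave the X-linked genes and the neighbours of a gene. Genes were taken only from probe sets with 1 symbol. Where a gene had more than 1 probe set (291 genes), the probe set with the highest mean over all arrays was kept, which left 18166 genes, with no filter on dim probe sets.

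Groups came from the sample titles. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a single fit of all 10 arrays with a mean per group, so that the groups shared an estimate of the spread per gene. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The comparisons were under-developed against normal testes of obese rats, normal testes of obese against lean rats, and under-developed testes of obese rats against normal testes of lean rats. Differences of single arrays were taken from the mean of the normal obese arrays. Summaries and plots were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

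The tests, the gene lists and the rule for naming genes were fixed before the data were examined. The lists covered spermatogonia, spermatocyte and meiosis, piRNA and germ plasm, spermatid acrosome and chromatin, sperm tail and flagellum, Sertoli cell, blood-testis barrier junctions, Leydig cell and steroidogenesis, cholesterol synthesis, peritubular myoid and smooth muscle, fibroblast and extracellular matrix, endothelial cell, macrophage, lymphocyte, mast cell, antigen presentation, inflammation and complement, antioxidant defence, apoptosis, leptin and insulin signalling, fatty acid metabolism, adipocyte, epididymis epithelium, rete testis and ciliated duct, red blood cell, stress response and immediate early, cell cycle, cytosolic ribosomal protein and X-linked genes. Some genes stand in more than 1 list, such as Kit among spermatogonia and mast cell genes. Lists were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, with adjustment over the lists, and beside it with an estimated correlation, with fry and with a two-sided exact permutation test of the list mean per array. Members were also counted after adjustment of their limma p over the genes of their list alone. These counts were not in the plan and were not adjusted over the lists.

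For each comparison the rule named the 10 genes with the largest rise and the 10 with the largest fall among those that passed and did not overlap between groups, leaving out unnamed loci, microRNA and olfactory receptor symbols starting with Olr. Where none qualified, it named the 5 with the smallest p in that direction. It also named up to 4 members of each list with the largest change, the first 3 members of the Sertoli, Leydig and spermatid lists, and 20 genes chosen in advance for their role in obesity or the testis, of which 18 were measured. The text gives a selection of these. Of the genes chosen in advance, Lepr was not analysed here and another is not reported here. Kremen1 is the gene called in the fit of the obese and lean normal arrays alone.

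On simulated data with 200 changed genes among 18166, the fit recovered 54% of changes of 1 log2 and 87% of changes of 3 log2 for under-developed against normal testes of obese rats, with 15 false calls. For obese against lean normal testes it recovered 42% and 88%, with 6 false calls. Camera called 5 of 5 shifted lists and 0 of 15 unshifted lists. The simulated arrays did not include an array that stands apart from its group.

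The alternatives were centring each array on its median, on the ribosomal protein list or on the Sertoli list, quantile normalization again, an offset of 50 before log2 in place of another background correction, filters on dim genes at the 25th percentile and at the median, the mean of a gene's probe sets, every probe set, moderation with trend and robust settings, array weights, a fit of only the 2 groups compared, the replicate number as a block, a 2-fold threshold, and leaving out each array. The fit without under-developed replicate 4 was taken further after the data had been seen.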

Results

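Gene expression was measured in testes of Zucker rats, a model of inherited obesity in which fa/fa animals carry a mutated leptin receptor, on 10 Affymetrix rat arrays with biotin-labelled RNA. The arrays comprised normally developed testes of obese rats (4 arrays), under-developed testes of obese rats (4 arrays) and normally developed testes of lean rats (2 arrays), and all rats were labelled as 14 weeks old and sexually mature. The labels of the lean rats also carry the fa/fa model and the text for obese animals, so their genotype was not settled. The samples are called biological replicates, but nothing says whether each testis came from a separate animal, so p-values measure the spread between these samples only. Each array gave log2 values for 36685 probe sets between 2.28 and 14.0, with array medians from 6.14 to 6.38, and 18166 named genes were tested. The number of arrays, above all the 2 of lean rats, limits the precision.

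Within the under-developed group, 3 arrays differed widely from the normal testes and 1 did not. Over genes, which are not independent replicates, the 6 arrays of normally developed testes correlated with each other at r between 0.994 and 0.997 (15 pairs). Under-developed replicates 1, 2 and 3 correlated with them at a mean r of 0.856, 0.946 and 0.731, and replicate 4 at 0.995. Relative to the mean of the normal obese testes, 2819 genes were at least 2-fold higher and 2835 at least 2-fold lower in under-developed replicate 1. These counts were 1373 and 1122 in replicate 2, 3496 and 3060 in replicate 3, and 7 and 1 in replicate 4. The median SD per gene was 0.355 log2 among the under-developed arrays, 0.102 among the normal obese arrays and 0.0765 between the lean arrays. For that reason the differences from the normal obese mean are given below for each under-developed array, in the order of replicates 1 to 4.

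The comparison named by the series title set under-developed against normally developed testes, within obese rats. In under-developed replicates 1 to 3, genes of meiosis, of spermatids and of the sperm tail were far lower, and genes of macrophages, extracellular matrix, Sertoli cells and Leydig cells were higher. The mean of the sperm tail list differed from the normal obese testes by −2.26, −0.87, −4.30 and −0.01 log2 in under-developed replicates 1 to 4. The mean of the macrophage list differed by 1.75, 1.06, 1.67 and −0.04 log2. The arrays of normal obese testes spread around their mean by an SD of 0.018 for the sperm tail list and 0.15 for the macrophage list (n = 4). With all arrays, limma called 0 of 18166 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.0702. At an unadjusted p under 0.05 there were 8470 genes (4425 higher and 4045 lower) in limma, against 908.3 expected by chance, and the fit of these 2 groups alone also called 0, with 7435 at an unadjusted p under 0.05. The values of the 2 groups did not overlap for 1351 genes higher and 1884 lower in under-developed testes, 17.8% of the genes, where chance gives 2.86%. That chance value treats all arrays as interchangeable, which replicates 1 to 3 were not. Replicate 1 lay above all 6 normal arrays for 40.7% of genes and below them for 37.8%. Replicate 4 did so for 17.8% and 18.6%, against 14.3% each by chance. The lack of overlap therefore does not show that replicate 4 differs from the normal testes. Without under-developed replicate 4, limma called 10171 genes, of which 5381 rose and 4790 fell. This balance depended on scaling, with 4490 higher and 5411 lower after median centring, 4722 and 5379 after quantile normalization, 2151 and 12947 with arrays centred on the ribosomal protein list, and 1543 and 14290 on the Sertoli list. Leaving out each array in turn was planned, but replicate 4 was singled out after its values had been seen, so these calls are not independent evidence. Counts of list members without replicate 4, given below, are to be read beside the 10171 of 18166 genes called over all.

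**Figure D1:**
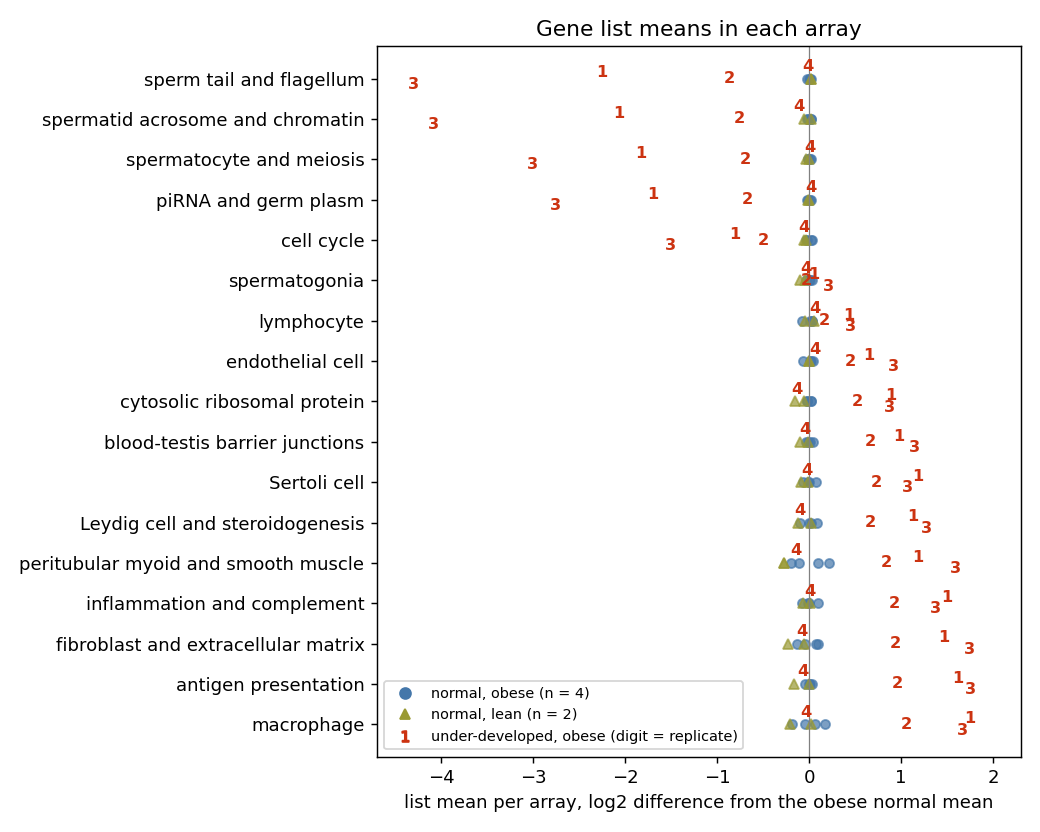
Mean of each gene list per array, as the log2 difference from the mean of the normal obese testes (horizontal axis), for each list. Circles are normal obese arrays, triangles normal lean arrays and digits the under-developed replicates. Replicate 4 lies near 0 for every list, while replicates 1 to 3 reach −4.30 for the sperm tail list and 1.76 for the antigen presentation list.

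Of the 29 lists, 4 germ cell lists had the lowest means in the under-developed testes. All 4 fell as sets in limma camera, namely spermatocyte and meiosis (40 genes, mean log2 difference −1.38, adjusted p = 5.84e-09), piRNA and germ plasm (25 genes, −1.28, adjusted p = 1.73e-05), spermatid acrosome and chromatin (36 genes, −1.75, adjusted p = 5.84e-09) and sperm tail and flagellum (42 genes, −1.86, adjusted p = 2.22e-09). Each of these had an adjusted p = 0.493 with an estimated correlation. In all arrays 0 of their genes passed over all genes tested; adjusted over the list alone, 14 piRNA genes were lower and 1 higher, and 0 genes of the other lists passed. Without replicate 4, 35 spermatocyte, 22 piRNA, 33 spermatid and 39 sperm tail genes fell in limma, and 1 piRNA gene rose. Spem1, which acts in shaping the elongating spermatid, stood at 12.23 ± 0.05 (SD, n = 4) in normal obese testes and differed by −4.62, −1.17, −5.33 and −0.02 log2 in under-developed replicates 1 to 4. The transition protein gene Tnp2 differed by −4.08, −0.60, −4.30 and −0.12, and the protamine gene Prm1 by −2.89, −0.26, −2.72 and −0.04. Acr, which encodes the acrosomal protease acrosin, differed by −2.46, −1.33, −5.11 and 0.00. Among earlier germ cell genes, the synaptonemal complex gene Sycp3 differed by −2.04, −0.27, −3.70 and −0.15, the PIWI gene Piwil1 by −4.05, −1.09, −4.55 and 0.01, and the RNA helicase gene Ddx4 by −1.45, −0.45, −4.37 and 0.02. In the fit of all arrays the log2 differences were −2.79 ± 1.06 (SE) for Spem1, −1.54 ± 0.69 for Sycp3 and −1.56 ± 0.81 for Ddx4, with limma adjusted p from 0.0778 to 0.154.

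The spermatogonia list, which marks the stem and progenitor stages of the germ line, did not pass as a set (22 genes, mean 0.05 log2, limma camera adjusted p = 0.798, which pointed down while the mean lay above 0). Its members went both ways. Kit, the receptor of differentiating spermatogonia that Leydig and mast cells also carry, differed by 2.04, 1.37, 2.52 and −0.03 in replicates 1 to 4. Zbtb16, a gene of undifferentiated spermatogonia, differed by 0.61, 0.30, 1.95 and −0.20, with a fitted difference of 0.67 that became −0.07 when arrays were centred on the Sertoli list. Sohlh2 and Stra8, which act in spermatogonial differentiation and entry into meiosis, differed by −1.39, −1.08, −2.52 and −0.05 and by −1.24, −0.30, −1.54 and −0.02. Adjusted over the list alone, 0 of the 22 genes passed with all arrays. Without replicate 4, 5 rose and 5 fell over all genes.

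Sertoli cell genes rose as a set (33 genes, mean 0.74 log2, limma camera adjusted p = 2.91e-04, adjusted p = 0.493 with an estimated correlation), a mean that centring on the ribosomal protein list reduced to 0.20. Junction genes of the blood-testis barrier rose as a set too (29 genes, mean 0.69, limma camera adjusted p = 2.22e-03, adjusted p = 0.493 with an estimated correlation), but their mean was −0.05 with arrays centred on the Sertoli list. Over all genes 0 members of either list passed with all arrays; adjusted over the list alone, 19 Sertoli genes were higher and 2 lower, and 12 junction genes were higher and 1 lower. Without replicate 4, 23 Sertoli genes rose and 2 fell, and 18 junction genes rose and 2 fell. The follicle-stimulating hormone receptor gene Fshr differed by 2.39, 1.62, 2.38 and 0.27 log2, the tight junction gene Cldn11 by 2.49, 2.13, 2.86 and 0.00, and the Kit ligand gene Kitlg by 2.73, 1.73, 2.67 and 0.05. Cst12, a cystatin gene, differed by 2.89, 2.45, 2.74 and −0.03, and Itga6, an integrin gene, by 3.48, 2.78, 3.76 and 0.01. Other Sertoli genes had smaller differences, given here from the fit of all arrays, which includes replicate 4. The fitted difference was 0.26 ± 0.14 (SE) for Sox9, −0.27 ± 0.09 for Amh and 0.09 ± 0.13 for Inhbb, and centring on the Sertoli or ribosomal protein list turned Sox9, Sox8 and Inhbb negative.

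Leydig cell and steroidogenesis genes rose as a set (34 genes, mean 0.74 log2, limma camera adjusted p = 4.46e-04, adjusted p = 0.493 with an estimated correlation), a mean of 0.20 with arrays centred on the ribosomal protein list and of about 0 on the Sertoli list. Over all genes, and adjusted over the list alone, 0 passed with all arrays; without replicate 4, 21 rose and 1 fell. The members differed. Insl3, the Leydig cell hormone of testicular descent, stood at 10.03 ± 0.14 (SD, n = 4) in normal obese testes and differed by 2.11, 1.80, 2.84 and −0.35 log2 in under-developed replicates 1 to 4. Star, which carries cholesterol into mitochondria, differed by 1.66, 0.70, 1.91 and 0.09, and the luteinizing hormone receptor gene Lhcgr by 1.64, 0.54, 1.44 and −0.04. Cyp11a1, the enzyme of the first step of steroid synthesis, differed by 0.62, 0.12, −0.01 and −0.80, and its fitted difference of −0.02 ± 0.30 (SE) changed sign without under-developed replicate 4 (0.24) or normal obese replicate 3 (0.14). Hsd17b3, which makes testosterone, differed by −0.14, 0.35, 0.73 and −0.09, with a fitted difference of 0.21 that centring on the Sertoli or ribosomal protein list turned negative. Cyp17a1 varied widely among normal obese testes already (7.91 ± 1.30, SD, n = 4).

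Immune and inflammatory genes were higher in under-developed replicates 1 to 3. In limma camera the macrophage (29 genes, mean 1.11 log2, adjusted p = 2.62e-05), antigen presentation (18 genes, 1.07, adjusted p = 5.84e-04) and inflammation and complement lists (38 genes, 0.95, adjusted p = 1.73e-05) rose as sets, and their means stayed above 0 under each centring. Each had an adjusted p = 0.493 with an estimated correlation. With all arrays 0 of their genes passed over all genes; adjusted over the list alone, 22 macrophage genes were higher and 2 lower, 12 antigen presentation genes higher and 1 lower, and 22 inflammation genes higher. Without replicate 4, 23 macrophage genes rose and 2 fell, 14 antigen presentation genes rose, and 25 inflammation genes rose and 1 fell. Lyz2, the lysozyme gene of macrophages, differed by 4.00, 2.12, 3.93 and −0.32 log2, the scavenger receptor gene Cd163 by 3.11, 2.16, 3.33 and 0.31, and Cd68 by 2.55, 1.64, 2.99 and −0.21. The class II invariant chain gene Cd74 differed by 3.49, 2.16, 3.38 and −0.12. Spp1, the osteopontin gene, differed by 3.96, 3.05, 5.07 and −0.18, and Serping1, the inhibitor of complement C1, by 4.34, 3.34, 4.09 and −0.06. The lymphocyte list rose by less (22 genes, mean 0.27, limma camera adjusted p = 0.0396, adjusted p = 0.104 without replicate 4, adjusted p = 0.493 with an estimated correlation), and its mean was negative with arrays centred on the ribosomal protein or Sertoli list (−0.27 and −0.47). Without replicate 4, 10 members of the lymphocyte list rose and 2 fell. Among those that rose, Cd4 differed by 2.40, 0.92, 1.98 and −0.10, and arrays of testes do not show which cells carried it. Adjusted over the list alone, 0 members passed with all arrays.

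Genes of the interstitium and vessels were higher as well. The fibroblast and extracellular matrix list rose as a set in limma camera (43 genes, mean 1.02 log2, adjusted p = 1.27e-06), as did the peritubular myoid and smooth muscle list (17 genes, 0.87, adjusted p = 5.12e-04). The endothelial list rose by less (19 genes, 0.52, adjusted p = 1.56e-03 in limma camera) and its mean was −0.02 and −0.22 with arrays centred on the ribosomal protein and Sertoli lists. Each of the 3 lists had an adjusted p = 0.493 with an estimated correlation. With all arrays 0 of their genes passed over all genes; adjusted over the list alone, 27 matrix genes were higher and 2 lower, 12 endothelial genes were higher, and 0 myoid genes passed. Without replicate 4, 34 matrix genes rose and 2 fell, 14 myoid genes rose, and 13 endothelial genes rose. Timp1, an inhibitor of matrix proteases, differed by 3.85, 3.21, 3.74 and −0.37 log2, the laminin gene Lamc1 by 3.06, 2.32, 3.05 and −0.08, and the proteoglycan gene Bgn by 3.11, 2.47, 3.12 and −0.11. The muscle filament gene Des differed by 2.37, 1.72, 2.28 and −0.05, and the endothelial cadherin gene Cdh5 by 2.04, 1.39, 2.21 and 0.05.

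**Figure D2:**
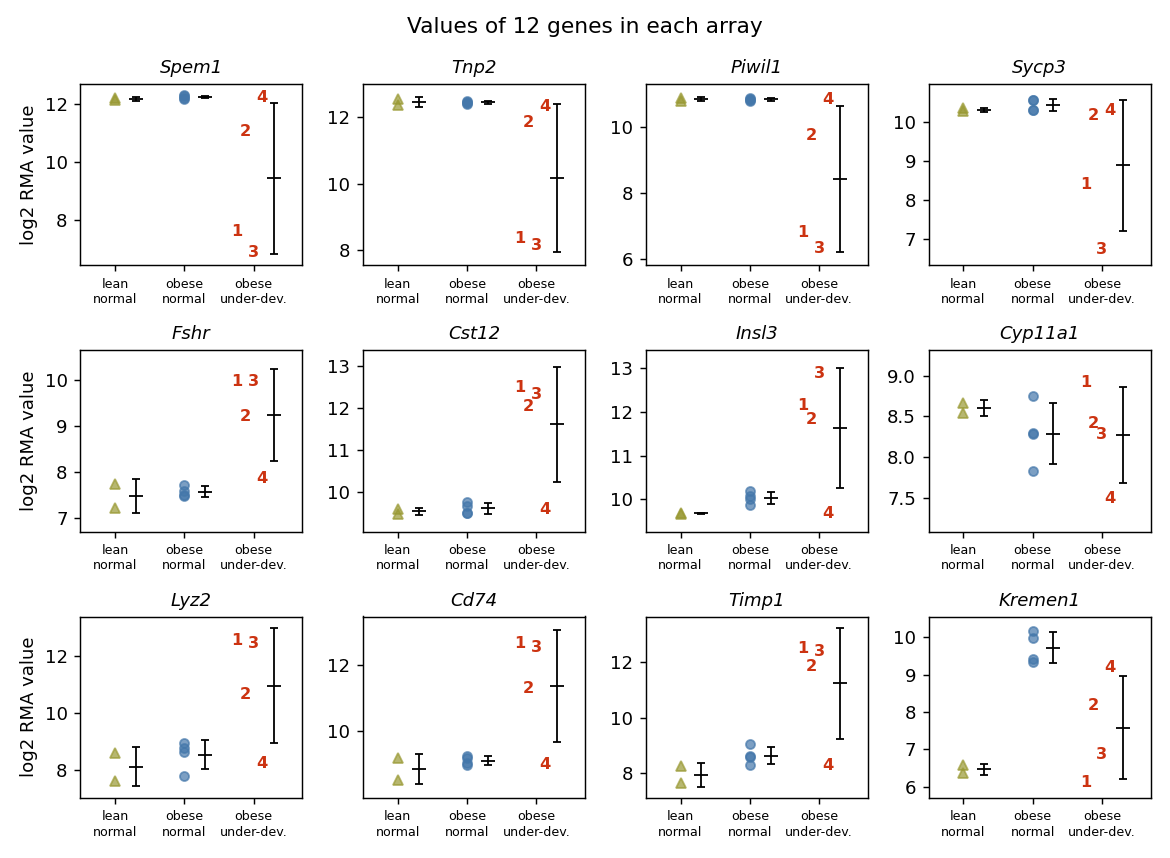
Log2 values of 12 genes in each array, with groups on the horizontal axis and a vertical scale per gene; circles and triangles are normal arrays, digits are the under-developed replicates, and bars show the group mean ± SD (n = 2, 4 and 4). Spem1 differed from the normal obese mean by −4.62 and −5.33 in replicates 1 and 3 and by −0.02 in replicate 4, and Kremen1 separates the lean from the normal obese testes.

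The leptin and insulin signalling list, chosen because of the obesity model, rose as a set (36 genes, mean 0.61 log2, limma camera adjusted p = 4.91e-03, adjusted p = 0.493 with an estimated correlation), with a mean of −0.13 when arrays were centred on the Sertoli list. With all arrays 0 genes passed over all genes; adjusted over the list alone, 19 were higher and 4 lower. Without replicate 4, 24 rose and 6 fell. Jak2 and Stat3, which carry the signal of the leptin receptor, differed by 3.12, 2.26, 3.12 and −0.17 and by 3.11, 2.34, 3.13 and −0.12 log2. Slc2a3, a glucose transporter gene abundant in germ cells, differed by −3.36, −0.90, −4.83 and 0.08. Lep, the leptin gene, stood at 4.78 ± 0.07 (SD, n = 4), low on the array's scale, and its fitted difference was −0.08 ± 0.11 (SE). Lepr was not analysed here, because no probe set carried its symbol alone. The cell cycle list fell as a set (36 genes, mean −0.72, limma camera adjusted p = 3.11e-04, adjusted p = 0.493 with an estimated correlation). Without replicate 4, 23 of its genes fell and 5 rose, and adjusted over the list alone 0 passed with all arrays. The mitotic kinase gene Plk1 differed by −1.91, −1.23, −4.39 and −0.07, and Cdc20 by −2.27, −1.10, −2.83 and −0.19.

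Of 29 lists, 20 passed limma camera with its preset correlation, 15 upward and 5 downward. With an estimated correlation 0 passed, and in fry, which asks whether the genes of a list move on balance one way, 0 passed. In a two-sided exact permutation test of the list means, the spermatid, endothelial, lymphocyte, mast cell and cell cycle lists reached p = 0.0286, the smallest that 4 against 4 arrays allow, and 0 of 29 passed after adjustment (permutation adjusted p = 0.166).

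The genes with the smallest p in each direction all had a limma adjusted p of 0.0702, so none passed the test. A choice by p favours genes in which replicate 4 goes with the other 3 arrays, so their values do not show a change shared by the group. Kcna3, a potassium channel gene of lymphocytes and neurons, stood at 7.28 ± 0.07 (SD, n = 4) in normal obese testes and differed by −0.98, −0.77, −0.47 and −0.70 log2 in under-developed replicates 1 to 4. The fitted difference of Higd2al1 was −0.79 ± 0.13 (SE). Lcn1 differed by −0.94, −0.54, −0.54 and −0.86, Taf1b by −0.77, −0.66, −1.01 and −0.46, and Med27 by −0.79, −0.69, −0.74 and −0.34. Fam50a differed by 1.92, 1.16, 1.14 and 0.75. The fitted differences of Xkr5 (0.53), Moxd2 (0.63), Plpp2 (0.70) and Snrpe-ps1 (0.58) were negative with arrays centred on the Sertoli list.

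**Figure D3:**
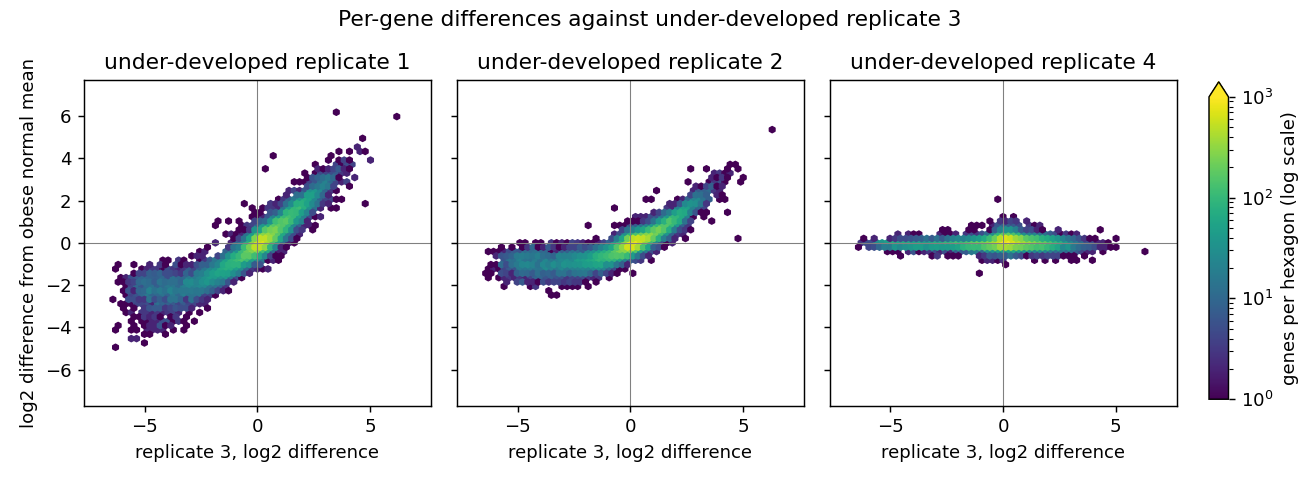
Log2 difference of each gene from the normal obese mean in under-developed replicates 1, 2 and 4 (vertical axes) against that in replicate 3 (horizontal axis), with colour for the number of genes per hexagon on a log scale. Over 18166 genes Pearson's r was 0.918, 0.834 and 0.0786.

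The comparison of normally developed testes of obese and lean rats bears on obesity without under-development. Germ cell lists differed little, with a mean difference (obese minus lean) of 0.017 log2 for the spermatid list and 0.016 for the spermatocyte list, both negative with arrays centred on the ribosomal protein or Sertoli list. One gene stood out. Kremen1, a co-receptor for Dickkopf proteins in Wnt signalling, was at 9.72 ± 0.41 (SD, n = 4) in obese and 6.46 ± 0.15 (SD, n = 2) in lean testes, a log2 difference of 3.26 ± 0.72 (SE) in the fit of all arrays. In under-developed testes it differed from normal obese testes by −3.63, −1.55, −2.87 and −0.53 in replicates 1 to 4. Among smooth muscle genes, of which 0 passed, Cald1 was at 8.80 ± 0.38 against 8.17 ± 0.07 in obese and lean testes, Actg2 at 6.72 ± 0.28 against 6.11 ± 0.26 and Tagln at 7.62 ± 0.34 against 7.07 ± 0.09 (SD, n = 4 and 2). With all arrays limma called 0 of 18166 genes at an adjusted p under 0.05 and 80 at an unadjusted p under 0.05, fewer than the 908.3 expected by chance. The spread shared with the under-developed arrays widens the errors, and limma on the 2 groups alone called 1 gene, Kremen1 (adjusted p = 0.0108), and 1141 at an unadjusted p under 0.05. The values did not overlap for 1399 genes higher and 1320 lower in obese testes, 15.0% of the genes, where chance gives 13.3%.

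In limma camera 3 of 29 lists rose in obese over lean testes, and none did so with an estimated correlation or in fry. These were peritubular myoid and smooth muscle (17 genes, mean 0.27 log2, adjusted p = 1.59e-03, p = 0.133 in the exact permutation test), cytosolic ribosomal protein (54 genes, 0.10, adjusted p = 3.08e-03) and spermatogonia (22 genes, 0.08, adjusted p = 0.0488), each with an adjusted p = 0.978 with an estimated correlation. The spermatogonia mean was −0.03 with arrays centred on the ribosomal protein list. The smallest p that 4 against 2 arrays allow in a two-sided exact permutation test is 0.0667, so no list could pass that test. Rpl10 and Rpl29 differed by 0.43 and 0.31 log2, and Uchl1 and Tspan8, genes of spermatogonia, by 0.28 and 0.29. Over all genes, and adjusted over the list alone, 0 members of these lists passed. Among the 18 genes fixed in advance that were measured, differences ran from −0.35 for Lhcgr to 0.46 for Hsd17b3. Insl3 differed by 0.36, Cyp11a1 by −0.31 and Lep by −0.15. Of the genes with the smallest p, Krtap4-6 differed by 0.74, Or7a38e by −0.56, Dlg5l13 by −0.94 and Plet1 by −0.96 log2, with a limma adjusted p of 1.00 with all arrays and of 0.744 in the 2 groups alone.

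Under-developed testes of obese rats were also set against normal testes of lean rats, groups that differ in both labels. The under-developed arrays are those of the first comparison, and lists were not tested here. The log2 difference was −1.53 ± 0.77 (SE) for Prm1, 1.95 ± 0.69 for Insl3 and 1.98 ± 0.72 for Cd68, and the differences of list means were −1.88 for the sperm tail, 0.13 for the spermatogonia and 1.20 for the macrophage list. Kcna3 was at 6.55 ± 0.21 (SD, n = 4) in under-developed and 7.57 ± 0.09 (SD, n = 2) in lean testes, a difference of −1.02 ± 0.15 (SE). Plet1 was at 4.30 ± 0.20 and 5.71 ± 0.37. Limma called 0 genes at an adjusted p under 0.05 (smallest adjusted p = 0.154), and 5776 genes had an unadjusted p under 0.05 (3186 higher and 2590 lower). In limma on these 2 groups alone 881 genes had an unadjusted p under 0.05, fewer than the 908.3 expected by chance, and the smallest adjusted p was 0.373. The values did not overlap for 2494 genes higher and 2679 lower, 28.5% of the genes, where chance gives 13.3%. This chance value also treats the arrays as interchangeable, so the share does not show that replicate 4 differs from the lean testes. Without under-developed replicate 4, limma called 8866 genes, 4646 higher and 4220 lower.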

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

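The tests of a swap, of a mild form, in all genes or in spermatid genes alone, and of a single wrong label for under-developed replicate 4, of the Leydig genes, and of germ cell share for Kremen1 were chosen after the result was seen.

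Under-developed replicate 4 carries the label of its group but lies close to the normal testes. A swap with a normal array needs a normal array with low germ cell genes, and the lowest spermatocyte list mean among the 6 normal arrays was −0.029 log2, which argues against it. A mild form of the change in replicates 1 to 3 over all genes is argued against by the slope of replicate 4 on their mean over genes, 0.013, inside the range of the normal arrays (−0.037 to 0.022). A mild form in spermatid genes alone stays open. Their list mean in replicate 4 was −0.11 log2, just below the normal arrays (−0.053 to 0.020). Of 36 genes, 20 lay below all of these and 0 above. Offsets of this size were not particular to spermatid genes. The ribosomal protein list, which rose in replicates 1 to 3, was at −0.13 in replicate 4, with 22 of 54 genes below all normal arrays. In lean replicate 1 that list was at −0.16, with 36 of 54 genes below the other normal arrays. A single wrong label or an unaffected testis may each account for the closeness of replicate 4 to the normal testes. They cannot be told apart, because both give a correlation with the normal arrays like theirs with each other (mean r of 0.995, against 0.994 to 0.997).

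The non-germ lists were higher by different amounts in under-developed replicates 1 to 3, for example 1.75, 1.06 and 1.67 log2 for macrophage and 0.65, 0.45 and 0.91 for endothelial genes. A lower share of germ cells alone would raise all other cell types alike, and it stays open for the lists. The planned comparison could not be run, because 0 endothelial genes lay above the median level. Of 15 pairs of 6 lists, 0 were apart by over 2 SE in all 3 arrays. That SE came from the spread between the genes of a list and was wide, 0.45 to 0.74 for 8 macrophage genes. The pairs therefore cannot decide the question. For Leydig genes a lower share of germ cells alone stays open too. Insl3 exceeded Cyp11a1 by at least 1.49 log2 in replicates 1 to 3, but this pair was picked for its values. Over 6 Leydig genes fixed in advance the range within an array was at least 1.67 in these replicates, against 0.88 to 1.67 in the normal arrays. The 6 include Cyp17a1, which varied widely among normal obese testes, so this range cannot decide the question. Compression of dim probe sets may account for part of the differences between lists. The rise increased with the level over 214 genes (Spearman's rho of 0.368, across genes, which are not independent replicates). Within the macrophage list this was not seen. Its 8 members above the median level rose by 1.75, 1.07 and 1.60 log2 in replicates 1 to 3, like the whole list. In each of the other lists compared, members above the median level rose by more than the whole list. For extracellular matrix these values were 1.84, 1.29 and 2.01 against 1.46, 0.94 and 1.74. With 0 endothelial genes above the median level, the part of compression in the gap between macrophage and endothelial genes was not settled. A change in the Leydig cells themselves was not tested.

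Kremen1 was higher in normal testes of obese than of lean rats by 3.26 log2. More germ cells in the obese testes are argued against by the spermatid list mean, which differed by 0.017 log2. A difference over the whole chromosome region is argued against by the 10 nearest genes tested, whose largest difference was 0.17 (Xbp1). An effect of obesity, and a strain difference at the gene or its probes, remain as untested explanations, with 2 lean arrays.

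Among splits of the 8 arrays of obese rats into groups of 4, 35 of 35 gave at least the 0 genes called by limma (highest other 0), as any split must, so that count says nothing of chance, while 8470 genes had an unadjusted p under 0.05. That count was reached by 1 of 35 splits, the real one, which is the smallest share possible. The share, under 0.05, met the rule set in advance, but by a narrow margin that does not exclude chance for the labelled groups. The 4 splits with a normal obese array in place of under-developed replicate 4 gave 7808 to 8272, so the count reflects replicates 1 to 3 and hardly sets the labelled groups apart from these splits. Without replicate 4, 1 of 35 splits, the real one, gave 10171 genes and the highest of the others 0, but this is no test of chance, because the array was left out for its values.

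Of 292 series of 4 arrays, 10 had a highest or lowest array whose gap to the next, divided by the range, exceeded Dixon's 95% critical value for 4 samples (3.42%). Chance gives about 1 in 20 only for independent series not picked on their values. Many of these genes were named for their change and some lists share genes, so the 3.42% is no test of chance. The rule also misses replicate 4 where replicates 1 to 3 spread widely, as in the sperm tail list (−2.26, −0.87, −4.30 and −0.01 log2). Among normal obese arrays the gap divided by the range was 0.992 for the mast cell list mean, 0.948 for Spem2, 0.966 for Piwil2, 0.950 for Sox9, 0.842 for Aldh1a1 and 0.837 for Fam50a. Among under-developed arrays it was 0.847 for Cst12, 0.862 for Clu, 0.869 for B2m and 0.849 for Timp1, each with replicate 4 apart.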

How the results depend on the processing

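The results without under-developed replicate 4 and their alternatives were chosen after the result was seen. For under-developed against normal testes of obese rats, limma called 0 genes under all alternatives except 3: 8670 with arrays centred on the Sertoli list (578 higher and 8092 lower), 9862 with array weights (replicate 4 had a weight of 0.0619), and 0 to 10171 over leaving out each array, with replicate 4 as the array that decides. Against lean testes it called 9620 with array weights and 0 to 8866 over leaving out each array, again by replicate 4 alone. For obese against lean normal testes it called 1 gene with array weights, 1 in the fit of the 2 groups alone and 0 on leaving out any array. Centring on the ribosomal protein or Sertoli list moved the median of all genes from 0.062 to −0.48 or −0.68 log2 by construction. Without replicate 4 the 10171 genes (52.9% higher) became 15833 with Sertoli centring (9.75% higher), 15098 with ribosomal protein centring (14.2% higher), 15513 over every probe set, 6218 with array weights, 5092 with a 2-fold threshold and 9057 to 11248 on leaving out a further array. The 20 lists called for under-developed testes became 0 with an estimated correlation, 0 in fry and 19 to 20 on leaving out an array. The 3 called for obese against lean testes became 0, 0 and 2 to 6 (5 without normal obese replicate 4, 6 without under-developed replicate 4). Without replicate 4 the 20 became 0 with an estimated correlation and 24 in fry.

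With the replicate number as a block, limma called 0 genes in each comparison, 8684 without replicate 4, and 20 lists for under-developed and 10 for obese against lean testes. Deviations of same-numbered arrays correlated at 0.077, 0.007, 0.024 and 0.260 between normal obese and under-developed arrays. Between normal obese and lean arrays they correlated at 0.135 and −0.056. The large differences between the under-developed arrays could hide a pairing, so these values do not decide it. The numbers were not taken to pair samples, because the labels do not say that they do. A block for slide or scan date was not run, since none was given. Signal over background was not available per probe set, and dim genes such as Lep may be compressed (rho of 0.368 of rise on level).

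Sertoli centring reversed Zbtb16 (−0.074), Sox9 (−0.48), Sox8 (−0.30), Inhbb (−0.65), Hsd17b3 (−0.53), Xkr5 (−0.21), Moxd2 (−0.12), Plpp2 (−0.039) and Snrpe-ps1 (−0.16). Ribosomal protein centring reversed Sox9 (−0.28), Sox8 (−0.097), Inhbb (−0.45), Hsd17b3 (−0.33) and Xkr5 (−0.0093). Array weights reversed Inhbb (−0.036) and Cyp11a1 (0.40), and Cyp11a1 ranged from −0.23 to 0.24 on leaving out each array (0.24 without under-developed replicate 4, 0.14 without normal obese replicate 3) and was lower by enough to pass with Sertoli centring (−0.76). Beyond the shift that centring brings by construction, the cause was not tested.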

Other observations

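The test of a mixture of tubules was chosen after the result was seen. Ribosomal protein genes were higher in under-developed replicates 1 to 3 but not in replicate 4 (54 genes, list means of 0.89, 0.52, 0.87 and −0.13 log2). The mean over all 4 was 0.54, and −0.20 with arrays centred on the Sertoli list (limma camera adjusted p = 1.49e-05, adjusted p = 0.493 with an estimated correlation). Rpl39 differed from normal obese testes by 3.20, 2.58, 3.24 and −0.35 in replicates 1 to 4. Antioxidant genes (43 genes, 0.56, −0.18 with Sertoli centring; limma camera adjusted p = 5.62e-03) and apoptosis genes (30 genes, 0.55, −0.19 with Sertoli centring; adjusted p = 7.33e-03) rose as sets, each with an adjusted p = 0.493 with an estimated correlation. Sod3, the extracellular superoxide dismutase, differed by 2.94, 2.33, 3.13 and −0.36, Txnrd3, a thioredoxin reductase gene of the testis, by −1.95, −0.80, −3.98 and −0.10, and Tnfrsf1a, a receptor of tumour necrosis factor, by 3.55, 2.61, 3.83 and −0.11. With all arrays 0 genes of these 3 lists passed over all genes; adjusted over the list alone, 18 antioxidant genes were higher and 4 lower, 10 apoptosis genes higher and 1 lower, and 0 ribosomal protein genes passed. Without replicate 4, 44 ribosomal protein genes rose and 2 fell, 25 antioxidant genes rose and 6 fell, and 18 apoptosis genes rose and 3 fell.

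Lipid lists went both ways and did not pass in limma camera: cholesterol synthesis (21 genes, mean 0.0043 log2, adjusted p = 0.569, pointing down) and fatty acid metabolism (46 genes, 0.12, adjusted p = 0.892), both negative with arrays centred on the ribosomal protein or Sertoli list. Adjusted over the list alone, 4 cholesterol genes were higher and 8 lower, and 15 fatty acid genes higher and 15 lower, against 0 over all genes. Fdps, an enzyme of the mevalonate pathway, differed by −2.21, −1.04, −2.55 and 0.00, Acsl1, which activates fatty acids, by −2.93, −1.34, −4.34 and −0.04, and Lpl, lipoprotein lipase, by 2.13, 1.13, 3.59 and −0.32. The stress response list (28 genes, 0.42, adjusted p = 0.0812 in limma camera, negative with either list centring) had 11 genes higher and 4 lower adjusted over the list alone and 0 over all genes, and its adjusted p in limma camera was 0.0324 without replicate 4 (0.494 with an estimated correlation). Other lists did not pass either: adipocyte (21 genes, mean −0.037 and median 0.049, adjusted p = 0.917 in limma camera), epididymis (25 genes, −0.27 and 0.040, adjusted p = 0.460), rete testis (16 genes, 0.028, adjusted p = 0.892), red blood cell (8 genes, 0.25 and median −0.061, adjusted p = 0.917) and mast cell (15 genes, 0.13, adjusted p = 0.569). In these 5 lists 0 genes passed over all genes or adjusted over the list alone, and the means of the rete testis, red blood cell and mast cell lists were negative with arrays centred on the ribosomal protein or Sertoli list.

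X-linked genes had a mean of 0.17 log2 (707 genes, −0.37 and −0.57 with ribosomal protein and Sertoli centring). As a set they had a limma camera adjusted p = 0.0128, and adjusted p = 0.493 with an estimated correlation. Without replicate 4, 291 X-linked genes were higher and 132 lower, where 5381 of all 18166 genes were higher and 4790 lower. With all arrays 0 X-linked genes passed over all genes or adjusted over the list alone. A hypothesis that they are higher as a set where germ cells are fewer asked for a mean above 95% of random lists matched on level in each of replicates 1 to 3. The percentiles among 10000 lists were 100, 100 and 87.4, and 0.01 in replicate 4, so the hypothesis was not met in replicate 3. It was set on the mean alone. In replicate 3 the X-linked mean was 0.17 log2 but the median 0.36, against medians of 0.27 and 0.13 in replicates 1 and 2. Medians were not compared with random lists. Normal arrays ranged from 0 to 100 themselves.

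The 1097 genes lower by more than 3 log2 in under-developed replicate 3 (median −4.17) had a median of −2.22 in replicate 1 and −0.97 in replicate 2, that is 21.5% and 51.0% of the normal level, and −0.064 in replicate 4, with quartiles of −2.63 and −1.83 in replicate 1 and −1.25 and −0.70 in replicate 2. A candidate explanation is a mixture of tubules with normal germ cells and tubules without them, which lowers all these genes by a like amount within an array. The slope on replicate 3 over these genes was 0.115 in replicate 1 and −0.020 in replicate 2, where a mixture needs under 0.2 and over 0.4 would argue against it, but over 143 members of 4 germ cell lists, not picked by replicate 3, it was 0.320 and 0.085, so the mixture stays open. A floor in replicate 3 may set the first slope and was not excluded. The median level of the 1097 genes there was 6.39, against 6.38 over the array's probe sets and 6.97 over the genes tested. Their fall was larger at a higher normal level (r of −0.45), short of a limit of 0.5 on the size of r tried for this. The spread of the 1097 genes, from −5.03 to −0.72 in replicate 1 against a median SD per gene of 0.102 in the normal obese arrays, goes against one equal amount for all genes, though an unequal response of the probe sets was not excluded, and single genes departed both ways, Acrv1 (−1.16) and Tdrd6 (−1.70) against Tnp2 (−4.08) and Spem1 (−4.62) in replicate 1, and Acrv1 (−0.49) and Tdrd6 (−0.56) against Spem2 (−1.78) and Fscn3 (−1.74) in replicate 2.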
